A study of Mus musculus with 8 samples.

How the data were processed

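RNA was sequenced from CAD cells, a mouse catecholaminergic neuronal line (Cath.a differentiated) kept undifferentiated in 8% fetal bovine serum. Per the labels, 4 libraries came from control cells and 4 from cells in which Pfn1, the gene for the actin-binding protein profilin 1, had been targeted with CRISPR/Cas9. The labels describe 4 biological replicates per condition and do not say whether these were separate clones or cultures, so p-values measure only the spread between these samples. The control libraries are titled wild type and carry a genotype label that reads as a control knockout; what that control received was not resolved here. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into stranded libraries.

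The authors deposited 1 table of 23038 mouse genes with an RPKM value (reads per kilobase of gene, scaled by the number of counted reads) for each library. The same deposited table holds the authors' log2 fold change, their mean log2 CPM over the libraries, and their p-value and adjusted p-value of the group comparison. The submitters' processing notes name CASAVA, RSEM, Bowtie, TopHat, edgeR and the human build hg19, with no role or order. The gene numbers and symbols in the table are those of mouse genes, so the genome used for alignment was left open and no coordinates are given. Settings, annotation and the use of strand in counting were not given in the sources used here. Of the gene numbers, 22959 were matched to RefSeq on GRCm38.p6, which was used only for names, gene classes, chromosomes and gene order. Of the symbols, 25 had been turned into dates, and these were renamed by their gene number. In all, 4907 genes were listed at 0 in every library.

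Depth is not stated in the table and was estimated. Low RPKM values were near whole multiples of what 1 read is worth. Among 4074 low genes, 97.5% gave whole reads within 0.02 of a read in every library above 0. The number of reads behind each gene's lowest value was chosen to fit, so genes above 0 in few libraries can pass by chance. The 97.5% therefore overstates the evidence. With the authors' mean log2 CPM, 1175 genes then gave estimates of 34100000, 34600000, 26300000 and 29100000 reads for control libraries 1 to 4, and of 29000000, 28600000, 33000000 and 30200000 for knockout libraries 1 to 4. At a given gene length, genes near 1 RPKM are backed by the fewest reads among those tested. The SE of the fit did not follow RPKM alone. The SE of the log2 fold change was 0.067 for Nckap1l, at 0.623 and 1.12 RPKM in control and knockout libraries. It was 0.291 for Mir674, at 2.31 and 7.82 RPKM. Adding 1 to RPKM before taking logs narrows both change and spread of genes near 1 RPKM, so these SEs do not compare precision directly.

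The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. The design assumed a table of counts and a count test, which was not run because the table held RPKM, so the replacement named in the same design was used: limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with a trended prior variance and group as the only term. A gene was tested if its mean reached 1 RPKM in at least 1 group, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Fold changes are on the log2(RPKM + 1) scale, which understates the change of genes with low values; folds of mean RPKM are named as such. No further scaling was applied to the RPKM values in the main fit. The CPM totals recovered from them were nearly equal, from 999959 to 999990 over the libraries, as division by counted reads makes them. They do not show whether the composition of the libraries differs, and other scalings were run as alternatives.

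In total 41 gene lists were written. Their members were matched by gene number, and counts for a list are of its tested members. Of the lists, 33 had at least 5 tested members. These were tested with limma camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. The named genes follow a rule: the profilin family; the 12 largest changes in each direction among called genes with a mean of at least 5 RPKM in the higher group and no overlap between the groups, leaving out unnamed models and pseudogenes; in each list described, up to 4 called members with the largest change and at most 3 in 1 direction; and the 5 smallest p-values in each direction. Genes outside that rule are named where marked as chosen after their values were seen, and some genes and 1 list that the rule takes in are not reported here.

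The fit was tested on simulated read counts made from these means and depths, with 200 genes changed by known folds among 11287 tested. Every gene was given the same chosen spread between libraries (dispersion 0.003), and genes varied independently. The fit recovered 70% of the genes changed 1.25-fold, 98% of those changed 1.5-fold and 100% of those changed 2-fold or 4-fold, with 13 false calls. These figures hold for that setting, which has no variation shared by many genes of a library, and may not hold for the real libraries. Alternatives covered scaling, pseudocount, filter on low values, variance estimate, replicate number as a block, and leaving out each library. Values on the log2(CPM + 0.5) scale, leaving out chromosome 2, and leaving out both libraries that stand apart were added after seeing the data. The gene lists were not retested with upper-quartile scaling, either alternative pseudocount, no filter on low values, the stricter RPKM filter or the robust variance estimate. Ranges given for lists over the camera alternatives with the preset correlation cover 15 settings and leave those out. All 35 splits of the 8 libraries into 4 and 4 were fitted as well.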

Results

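The data are 8 RNA-seq libraries from mouse CAD cells, 4 from control cells and 4 from PFN1 knockout cells, at an estimated 26300000 to 34600000 reads each. The only comparison the labels give is knockout against control, and it asks which transcripts differ once Pfn1 has been targeted. The precursor ribosomal RNA Rn45s took 13.92, 13.19, 14.18 and 9.15% of the reads in control libraries 1 to 4, and 11.86, 8.83, 9.1 and 8.4% in knockout libraries 1 to 4. On the first principal component (66.5% of the variance) the groups separated. On the second (14%) control library 4 lay at -11 and the other controls at -0.3 to 5.1, and knockout library 1 lay at 11.5 and the other knockouts at -6.4 to 1.7. Knockout library 1 differed over 1.2-fold from libraries 2, 3 and 4 in 1775, 1581 and 632 genes, so it lay nearest to library 4. Knockout libraries 2 and 3 differed in 364 genes, and library 4 differed from them in 730 and 644.

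Pfn1 transcript fell in every knockout library, from 423 ± 16.4 RPKM in control cells to 139 ± 10.8 RPKM (SD, n = 4 each), or 32.9% of control. Its log2 fold change was -1.60 (SE 0.051, adjusted p = 3.7e-09, limma), so transcript remained in the cells labelled knockout. Pfn2, the neuronal profilin, rose from 30 ± 1.23 to 35.2 ± 0.786 RPKM (log2 fold change 0.22, adjusted p = 0.0011). Pfn4 lay under the filter, at 0.107 ± 0.0199 and 0.146 ± 0.0435 RPKM, and Pfn3 was listed at 0 in all 8 libraries.

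**Figure D1:**
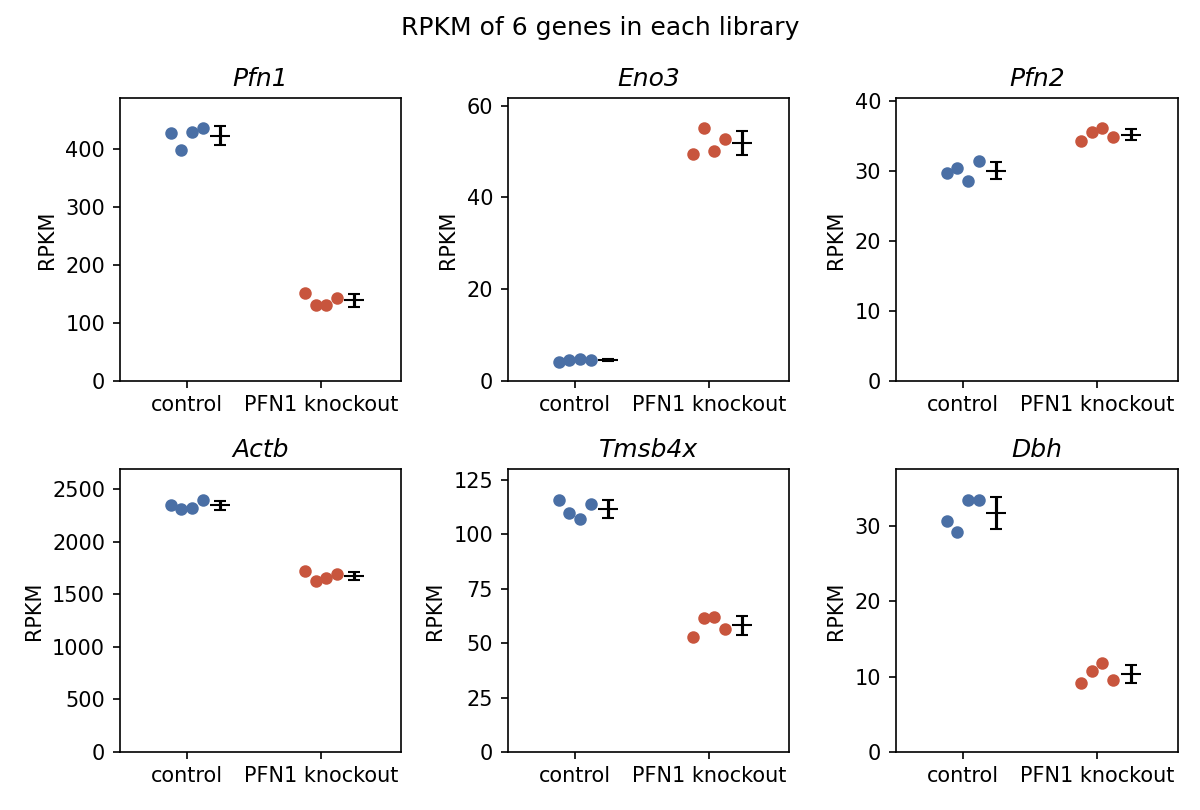
RPKM (vertical axes, each starting at 0) of 6 genes in the 4 control and 4 PFN1 knockout libraries; points are libraries, and the bar beside them is the mean with its SD. Pfn1 averages 423 RPKM in control and 139 RPKM in knockout libraries, while Eno3 averages 4.49 and 51.9 RPKM.

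The largest increase among the named genes was that of Eno3, the muscle enolase, from 4.49 ± 0.226 to 51.9 ± 2.58 RPKM, 11.6-fold in mean RPKM (log2 fold change 3.27, SE 0.051, adjusted p = 2.97e-12). Eno3 lies next to Pfn1 on chromosome 11, and in RefSeq on GRCm38.p6 the spans of the genes overlap; whether strand was used in counting is not stated, which leaves the level of Eno3 uncertain. Spp1, which encodes the secreted matrix protein osteopontin, rose 7.51-fold, from 1.99 ± 0.362 to 15 ± 1.49 RPKM. Prr9 rose 11.1-fold and Ptprq, a receptor-type phosphatase, 5.98-fold. Vip, the gene for vasoactive intestinal peptide, rose 4.31-fold, from 3.07 ± 0.514 to 13.2 ± 0.959 RPKM. Ctla2a rose 3.36-fold, and Ptgs1, the gene for cyclooxygenase 1, rose 3.11-fold. Mir674, a microRNA gene, rose 3.39-fold, from 2.31 ± 1.97 to 7.82 ± 1.37 RPKM, and 5.76-fold without control library 4, which stood at 5.16 RPKM. Its log2 fold change was 1.57 with an SE of 0.291, and what these reads say of the mature microRNA was not tested. Both Ptgs1 and Mir674 lie on chromosome 2. The other increases among the 12 largest were Fndc3c1 at 3.08-fold, Gpr115 at 2.95-fold, Malat1 at 2.67-fold and Clu, which encodes the chaperone clusterin, at 2.63-fold; in all 12 the adjusted p was at most 0.00113 (limma). Deptor, an inhibitor of mTOR, rose 2.45-fold, with a p-value among the 5 smallest for an increase.

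Hopx, a homeodomain protein gene, had the lowest ratio among the 12 largest decreases, from 5.70 ± 0.667 to 0.586 ± 0.216 RPKM, 10.3% of control. Bcmo1 fell to 17.3%, the actin-binding calponin gene Cnn2 to 19.7%, and Alpl, which encodes alkaline phosphatase, to 21.4% of control. Il11ra1, an interleukin 11 receptor chain, fell to 25.5% and Phlda2 to 30.9%. Dbh, which encodes dopamine beta-hydroxylase, fell from 31.7 ± 2.15 to 10.4 ± 1.22 RPKM, or 32.7% of control. Zcchc12 fell to 33.3%, the potassium channel gene Kcnk3 to 35.1%, the cadherin gene Cdh6 to 35.5% and the noncoding BC039966 to 36.3%. Every one of these decreases had an adjusted p of at most 0.000872 and no overlap between the 4 control and 4 knockout values.

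Across all genes, 5261 of 11465 tested were called, 3489 higher and 1772 lower in the knockout libraries (limma, adjusted p under 0.05). With median-of-ratios scaling the split was 2747 higher and 2723 lower, so the excess of increases depends on the scaling; upper-quartile scaling, and library sizes without ribosomal RNA and the 10 genes with most reads, each gave 55.3% higher against 66.3%. Most changes were small, with a median absolute log2 fold change of 0.27 among the called genes, and 91 genes changed at least 2-fold on the log2(RPKM + 1) scale, 55 up and 36 down. The values of the groups did not overlap for 4746 genes, 41.4% of those tested against 2.86% by chance. The authors' deposited table calls 6262 genes, 4250 higher and 2012 lower, over all its genes, and 5062 among the genes tested here. Of the 5261 called here 4882 are also called there, all in the same direction.

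Actin genes fell, while the lists of actin's partners went both ways. Actb, the cytoplasmic beta-actin gene, fell from 2340 ± 40.6 to 1670 ± 44.1 RPKM, and Tmsb4x, which encodes the monomer-binding thymosin beta 4, from 112 ± 3.74 to 58.2 ± 4.52 RPKM. Actg1 fell from 8.39 ± 0.733 to 3.62 ± 0.163 RPKM; it has near-identical copies, and how the counting divided reads between copies is not stated, so its level is uncertain. Of 34 tested genes for monomer binding, severing and capping, 9 rose and 5 fell (9 and 4 adjusted over the list alone), among them Gsn on chromosome 2, Cap2 and Vil1 upward. Of 35 genes of the Arp2/3 complex and its activators, 14 rose and 3 fell, in both counts, with Arpc5l and Wipf1 (both on chromosome 2) and Nckap1l up and Wasf1 down; the list did not pass camera (adjusted p = 0.368). Of 15 formins and Ena/VASP genes 3 rose, Inf2, Fhod1 and Diap1, and 3 fell, Daam2 with the largest change at 69.1% of control. Neither of the lists of monomer-binding and formin genes passed camera (adjusted p = 0.746 and 0.817). Of 26 bundling and crosslinking genes 9 rose and 4 fell, in both counts (adjusted p = 0.969), with the spectrin genes Spna2 (on chromosome 2) and Spnb2 up 1.52-fold and 1.22-fold and Lima1 down to 74.7%. The balance of these lists depends on the scaling: with median-of-ratios scaling 8 rose and 10 fell in the monomer-binding list, 8 and 8 in the Arp2/3 list, 3 and 4 in the formin list, and 6 and 8 in the bundling list. Without control library 4 and knockout library 1, 6 formin and Ena/VASP genes rose and 3 fell.

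The myosin II and tropomyosin list moved down by camera (adjusted p = 0.0423), with 3 of 19 genes higher and 6 lower, in both counts, and the adjusted p was 0.833 with an estimated correlation. Cnn2 and Myl12a, a myosin light chain gene, fell, while Cald1, which encodes caldesmon, rose 1.51-fold. The adjusted p was 0.0206 to 0.0952 over the camera alternatives with the preset correlation, highest without the genes of chromosome 2. It was 0.0915, 0.0578, 0.059 and 0.0557 without control library 1, control library 2, knockout library 1 or knockout library 2. Targets of MRTF and SRF, the transcription factors regulated by free actin monomer, went both ways, 9 of 25 higher and 10 lower in both counts (adjusted p = 0.14). Among them Cnn2 and the fibronectin receptor chain Itga5 fell, the latter from 17.1 ± 0.741 to 7.82 ± 0.306 RPKM, and Cyr61 rose from 0.689 ± 0.158 to 2.28 ± 0.43 RPKM. Without control library 4 and knockout library 1 the MRTF and SRF list moved down (adjusted p = 0.0274, the lowest of 0.0274 to 0.249 over the camera alternatives with the preset correlation). Of 30 integrin and focal adhesion genes 11 rose, including Itga1 and Itga3, and 11 fell, including Itga5 and Tns1, in both counts (adjusted p = 0.167). With median-of-ratios scaling 6 rose and 13 fell in the integrin list, and 7 and 11 in the MRTF and SRF list.

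Matrix genes moved down by camera (adjusted p = 0.0325), with 25 of 63 members tested. Of these 7 were higher and 11 lower, and 8 and 11 adjusted over the list alone. The adjusted p of this list was 0.833 with an estimated correlation, 0.158 with median-of-ratios scaling and 0.0745 without the genes of chromosome 2, in a range of 0.00814 to 0.158 over the alternatives with the preset correlation. Eln, the elastin gene, fell to 15.1% of control, Fbln2, which encodes fibulin 2, to 40.9% and Loxl2, a lysyl oxidase gene, to 41.2%, against the rise of Spp1.

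Genes of mitosis and cytokinesis fell together: of 39 tested, 31 were lower and 1 was higher, and 32 and 1 adjusted over the list alone (median log2 fold change -0.23, camera adjusted p = 1.6e-12). The adjusted p was 0.833 with an estimated correlation, the members' estimated correlation being 0.724, and at most 3.99e-11 over the camera alternatives with the preset correlation. Pttg1, which encodes securin, fell from 20.4 ± 1.13 to 12.2 ± 1.01 RPKM, and the cyclin B genes Ccnb2 and Ccnb1 fell to 60.9% and 67.1% of control. Cit, which encodes citron kinase, was the member that rose, from 4.36 ± 0.358 to 5.17 ± 0.473 RPKM, and its call was lost in 10 alternatives, 5 of which left out 1 library (adjusted p = 0.0641 to 0.122). The list's mean lay at -0.25, -0.042, -0.034 and -0.18 in knockout libraries 1 to 4 and between 0.084 and 0.192 in the control libraries, on a log2 scale centred on each gene's mean. Genes of DNA replication and the G1/S transition did not move as a list (7 of 37 higher, 5 lower, 7 and 4 adjusted over the list alone, adjusted p = 0.817), with Ccne1 up 1.53-fold, E2f1 and Pcna (both on chromosome 2) up, and Rrm1 down, and 7 higher and 9 lower with median-of-ratios scaling.

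**Figure D2:**
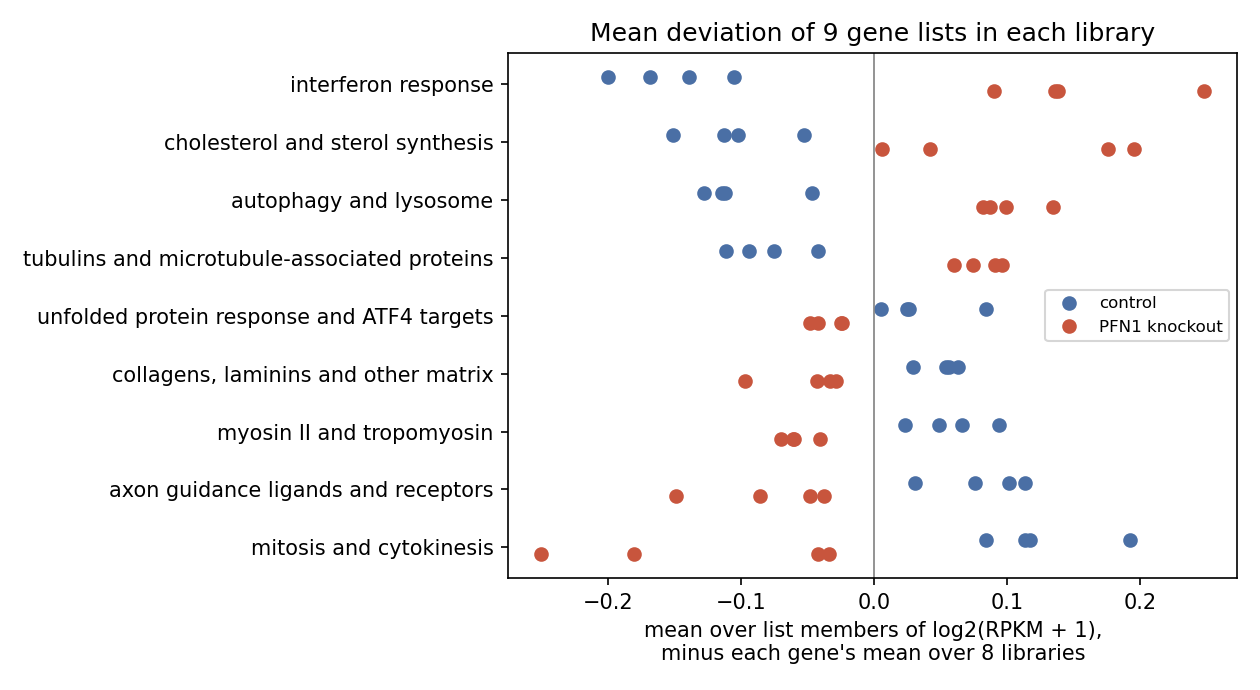
Mean over the members of each of 9 gene lists (vertical axis) of log2(RPKM + 1) minus the gene's mean over the 8 libraries (horizontal axis, log2), 1 point per library for 4 control and 4 PFN1 knockout libraries. In every list shown the 4 knockout points lie on 1 side of the 4 control points. Mitosis and cytokinesis spans -0.25 to 0.192. Such separation was also seen in lists that did not pass camera, among them the MRTF and SRF, cadherin and glycolysis lists. An exact permutation test on the library means gave p = 0.0286 for each separated list, the smallest these libraries can give. After Benjamini-Hochberg adjustment over the lists that p was 0.0524, so no list passed 0.05 in this test.

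Autophagy and lysosome genes rose: of 45 tested, 26 were higher and 1 lower, in both counts (median log2 fold change 0.17, adjusted p = 0.00258, and adjusted p = 0.833 with an estimated correlation). The cathepsin genes Ctsl and Ctsa rose 1.75-fold and 1.78-fold, and Map1lc3a, a gene for the autophagosome protein LC3, 1.65-fold; Ctsa and Map1lc3a lie on chromosome 2. Lamp2 was the member that fell, to 89.2% of control (adjusted p = 0.0488), a call lost in 10 alternatives, 6 of which left out 1 library (adjusted p = 0.0517 to 0.134). Sterol synthesis genes rose as well, 14 of 25 higher and 0 lower, and 16 and 0 adjusted over the list alone (median 0.18, adjusted p = 0.0062, and adjusted p = 0.908 with an estimated correlation). The sterol list's mean lay at 0.006, 0.176, 0.195 and 0.042 in knockout libraries 1 to 4 and between -0.151 and -0.053 in the control libraries, on the centred log2 scale. Pmvk, Cyp51 and Lss, enzymes of the pathway, rose 1.33-, 1.33- and 1.32-fold. With median-of-ratios scaling 19 autophagy and lysosome genes rose and 4 fell, and 11 sterol genes rose and 1 fell.

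Of 33 genes of the unfolded protein response and ATF4 program, 12 fell and 6 rose, and 13 and 6 adjusted over the list alone, or 17 and 3 with median-of-ratios scaling (median -0.09, adjusted p = 0.0062, and 0.833 with an estimated correlation). The members that fell most were Psat1 and Shmt2, enzymes of serine and glycine metabolism, at 70.7% and 71.1% of control, and the amino acid transporter gene Slc7a5, at 76.6%. Cebpb, on chromosome 2, rose 1.40-fold. Of 38 interferon response genes 13 were tested, of which 8 rose and 0 fell, in both counts (median 0.28, camera adjusted p = 0.0423). Those that rose were led by Psmb8, Ifi35 and Ifi27l1 at 2.18-, 1.93- and 1.78-fold. The interferon adjusted p was 0.833 with an estimated correlation and 0.0853, 0.09 and 0.0665 without control library 1, control library 4 or knockout library 1, in a range of 0.027 to 0.157 over the alternatives with the preset correlation.

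Axon guidance ligands and receptors moved down (median -0.12, camera adjusted p = 0.00242, and 0.833 with an estimated correlation), with 32 of 63 members tested. Of these 14 were lower and 6 higher, and 15 and 6 adjusted over the list alone. The netrin receptor gene Unc5a fell to 46.8% of control and the plexin genes Plxna4 and Plxnd1 to 51.4% and 56.9%, whereas Neo1, which encodes neogenin, rose 1.54-fold. Of 41 tubulin and microtubule-associated genes 18 rose and 3 fell, in both counts (median 0.11, adjusted p = 0.0325), with Tuba8 up 1.80-fold, Kif5c and Tubb4b up 1.51-fold and 1.44-fold and Mapre2 down to 86.3%. Kif5c and Tubb4b lie on chromosome 2, as do 7 of the 41 genes; 12 rose and 4 fell with median-of-ratios scaling; without that chromosome the adjusted p was 0.108, and it was 0.833 with an estimated correlation, 0.0814 with median-of-ratios scaling and 0.0607 without control library 4, in a range of 0.0152 to 0.108 over the alternatives with the preset correlation.

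Catecholamine and noradrenergic genes split, 8 of 21 higher and 8 lower, and 9 and 8 adjusted over the list alone (adjusted p = 0.969). The synthesis enzyme genes Dbh and Th fell, Th from 2.25 ± 0.404 to 0.773 ± 0.133 RPKM, while the granin genes Chgb and Scg2, whose products are stored in dense-core vesicles, rose. Chgb went from 162 ± 20.7 to 347 ± 15.5 RPKM and Scg2 from 42.3 ± 1.5 to 82.0 ± 1.47 RPKM; Dbh and Chgb lie on chromosome 2. Of 29 synaptic and secretory vesicle genes 13 rose and 3 fell, in both counts, or 9 and 4 with median-of-ratios scaling (adjusted p = 0.275), including Vamp1 up 2.44-fold, Snap25 (on chromosome 2) up, and Sv2c down. Among 30 neurite and neuronal differentiation genes 8 rose and 7 fell, in both counts, or 6 and 9 with median-of-ratios scaling (adjusted p = 0.699), with Stmn2 up 1.45-fold and the neural progenitor gene Nes down to 51.3%. Of 38 cadherins and protocadherins 14 were tested, of which 3 rose and 5 fell, in both counts (camera adjusted p = 0.165). With median-of-ratios scaling 2 rose and 5 fell. Celsr2 fell to 66.9% of control, and Ctnnd1, which encodes a catenin and lies on chromosome 2, rose 1.26-fold.

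Genes of chromosome 2 were shifted as a block. Their median log2 fold change was 0.26, against 0.04 for the genes of the other chromosomes, and 649 of the 947 tested were called higher and 36 lower. Chromosome 2 held 8.26% of the tested genes and 18.6% of the genes called higher. The median offset of its genes from the other chromosomes averaged -0.112 ± 0.002 in control and 0.113 ± 0.007 in knockout libraries (SD, n = 4 each; exact permutation p = 0.0286, two-sided, the smallest these libraries can give; 0.044 adjusted over 20 chromosomes). Chromosomes 4, 5, 6, 9, 10, 11, 12, 14, 16, 17, 18 and 19 reached the same p with smaller shifts. Of these, chromosome 18 had a median of 0.15 and chromosome 14 one of -0.03. The p-value therefore does not single out chromosome 2. No other chromosome median lay more than 0.09 from that of all tested genes. Without the genes of chromosome 2, 4507 genes were called, 2796 higher and 1711 lower.

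**Figure D3:**
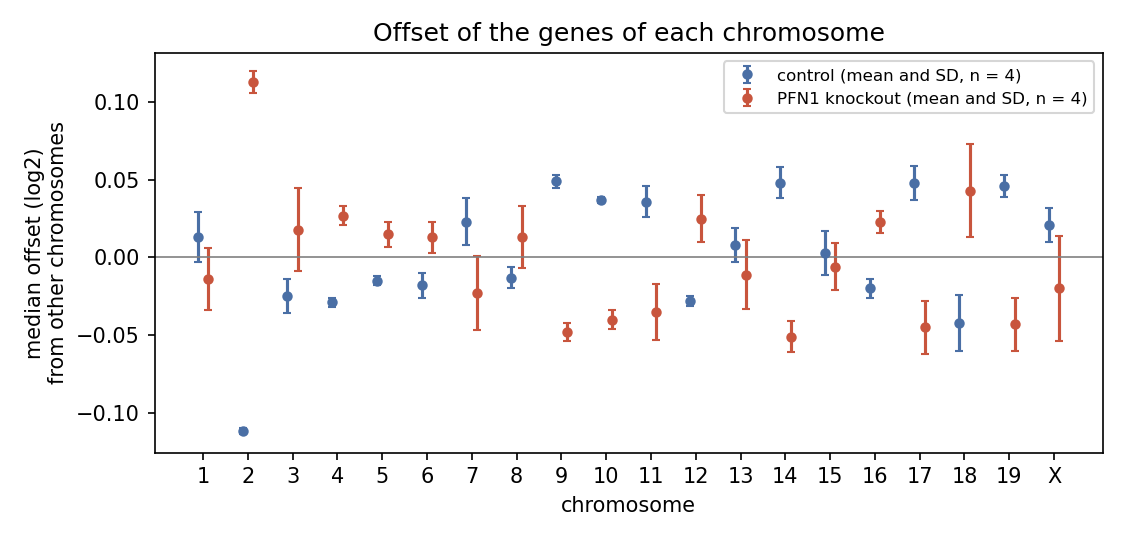
Median offset (vertical axis, log2) of the tested genes of each chromosome (horizontal axis) from the genes of the other chromosomes, as mean and SD over 4 control and 4 PFN1 knockout libraries. Chromosome 2 lies at -0.112 in control and 0.113 in knockout libraries, the widest separation.

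Long noncoding RNAs were called higher more often than protein-coding genes: 130 of 338 tested were higher and 21 lower, against 3293 higher and 1724 lower of 10856 protein-coding genes (Fisher's exact test on the called genes, two-sided, p = 3.58e-08; genes are not independent replicates). With median-of-ratios scaling the counts were 109 higher and 32 lower for long noncoding RNAs, and 2589 and 2657 for protein-coding genes. Malat1, an abundant nuclear RNA, stood at 292, 382, 322 and 631 RPKM in control libraries 1 to 4 and at 832, 1240, 1160 and 1110 RPKM in knockout libraries 1 to 4. Neat1, the scaffold of paraspeckles, rose from 1.31 ± 0.46 to 4.99 ± 0.783 RPKM. Rmrp, an RNA of RNase MRP, rose 1.30-fold, a call lost with no filter on low values (adjusted p = 0.0613). Rn45s was lower in the knockout libraries (log2 fold change -0.39, adjusted p = 0.0319) with overlapping values, and that call was lost in 8 alternatives, 6 of which left out 1 library (adjusted p = 0.0631 to 0.247 where lost). Of 17 structural noncoding RNAs on the list 6 were in the table and tested, of which 4 rose and 2 fell, in both counts (camera adjusted p = 0.353).

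The other lists did not pass camera. Oxidative stress genes had 13 of 25 higher and 1 lower, in both counts, or 8 and 4 with median-of-ratios scaling (adjusted p = 0.14), led by Srxn1 on chromosome 2 at 2.25-fold and G6pdx at 1.63-fold. The adjusted p of that list ranged from 0.0475 to 0.405 over the camera alternatives with the preset correlation and passed the threshold without knockout library 2 (0.0477) or 3 (0.0475). Cytosolic ribosomal protein genes had 24 of 78 higher and 3 lower, and 22 and 3 adjusted over the list alone (adjusted p = 0.187), or 15 and 7 with median-of-ratios scaling and 38 and 5 without control library 4 and knockout library 1; how the counting divided reads between these genes and their pseudogenes is not stated, so levels of single members are uncertain. Glycolysis genes had 8 of 23 higher and 6 lower, in both counts, or 7 and 7 with median-of-ratios scaling (adjusted p = 0.873), with Aldoc up and the lactate transporter gene Slc16a3 down. Immediate early genes had 9 of 24 higher and 6 lower, and 10 and 6 adjusted over the list alone, or 8 and 9 with median-of-ratios scaling (adjusted p = 0.834), with Klf2, Maff and Ier3 up and Dusp5 down. Targets of p53 had 4 of 21 higher and 5 lower, in both counts, or 3 and 6 with median-of-ratios scaling (adjusted p = 0.699), with Cdkn1a and Aen up and Ephx1 and Psrc1 down. Heat shock and chaperone genes had 7 of 23 higher and 5 lower, in both counts, or 4 and 5 with median-of-ratios scaling (adjusted p = 0.984), with Dnajb2 and Hspa8 up and Hsf2 and Chordc1 down. Camera sets a list against all other tested genes, and the median log2 fold change of all tested genes was 0.06. Its sign was downward for the monomer-binding, formin, immediate early, G1/S, p53, oxidative phosphorylation, glycolysis and heat shock lists, with medians above 0. The immediate early and heat shock medians, 0.09 and 0.07, were above 0.06 as well, so medians alone do not account for the sign. The neurite list had a median of 0.03 and a mean of -0.01. Nuclear-encoded genes of oxidative phosphorylation had 13 of 73 higher and 19 lower, and 12 and 19 adjusted over the list alone, or 8 and 24 with median-of-ratios scaling and 16 and 16 without control library 4 and knockout library 1 (adjusted p = 0.158, and 0.0331 to 0.273 over the camera alternatives with the preset correlation). That list passed, downward, with median-of-ratios scaling (0.0331), with library sizes without ribosomal RNA and the 10 genes with most reads (0.0488), and without control library 4 and knockout library 1 (0.0427). Mitochondrially encoded mRNAs had 0 tested genes. Of marker lists for other cell types, leukocyte and epithelial markers had 0 tested genes, glial and endothelial markers 1 each, and fibroblast and mesenchymal markers 4, of which Prrx1 fell and Twist1 rose.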

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

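Tests of the local neighbourhood, of paralog reads against a bound, of chromosome medians and of other splits were fixed before their results were seen; the tests of the paralog fold, overlapping reads, the gene beside Pfn1, expression and sequence trends, gene clusters, ribosomal RNA and scaling were chosen only afterwards.

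In 18 of 312 groups of 4 libraries checked, 1 library lay far from the other 3, where chance gives about 1 in 20 groups, or 16. Control library 4 was the one apart in 7 of them: Fndc3c1 at 5.46, Inf2 at 7.71, Stmn2 at 13.0, Rrm1 at 178, Hist1h2bh at 65.1, Hspa8 at 71.4 and Neat1 at 1.99 RPKM. In the other control libraries these were Bcmo1 at 4.42 and Celsr2 at 1.87 RPKM (library 1), Psrc1 at 5.64 and Ndufa2 at 86.0 RPKM (library 2), and Pink1 at 7.20 and Eno1 at 7.92 RPKM (library 3). In the knockout libraries they were Eln at 0.466 RPKM (library 1), Itga3 at 5.06 RPKM (library 2), Hist1h3i at 108 RPKM (library 3), and Ctsa at 40.5 and Cdc42ep2 at 0.626 RPKM (library 4).

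The real split of the libraries called 5261 genes and the highest of the other splits 0. Only 1 of the 35 splits, the real one, gave as many, the best result that 8 libraries allow. Every other split mixes the groups, so their difference widens the spread within each side and keeps calls few. A count near 0 was therefore likely beforehand, and the comparison cannot exclude chance differences between cultures or clones. By limma at an unadjusted p under 0.05 the real split gave 6103 genes. The other 34 splits gave at most 2519, where about 573 are expected by chance.

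Beside the edited gene Eno3 rose 11.6-fold. Reads shared with its paralogs had been given a bound beforehand, which Eno2 met with a log2 fold change of 0.51, but a comparison chosen afterwards argues against them: Eno3 exceeded both paralogs by at least 2.76, more than a fixed share of their reads allows. Reads of Pfn1 counted to the overlapping Eno3 would fall with Pfn1, while Eno3 rose by 3.27. The 10 tested genes nearest to Pfn1 did not change unusually as a block, at percentile 22.7 of windows of 10 neighbours, yet Rnf167, directly on the other side and named after its values were seen, rose from 10.5 ± 0.705 to 17.5 ± 0.968 RPKM, a change reached by 1.78% of tested genes. Further neighbours were also looked up after their values were seen. Beyond Rnf167, Slc25a11 and Pld2 were called higher (log2 fold change 0.24 and 0.37), and Mink1 and Psmb6 were not called. Beyond Eno3, Camta2 was called higher (0.18), and Spag7, Kif1c, Zfp3 and Rabep1 were not called. These values do not settle whether a local effect stops at the genes directly beside Pfn1. An effect on genes beside Pfn1, through the edit itself, stays open as a hypothesis. So does a response of Eno3 to the loss of profilin 1, which was not tested.

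Chromosome 2 genes were shifted up by 0.22 (log2) relative to other chromosomes, 1.17-fold. Trends with expression, GC content and transcript length amounted to -0.06 to 0.05 from the 5th to the 95th percentile of genes and to 0.002 between chromosome 2 and the others; removing them left 0.22, and within 5 equal classes of each property the shift was 0.16 to 0.26. In addition, 100% of the windows of 20 neighbouring genes lay above the median of the other chromosomes, so the values argue against such a trend and against a few clusters. A difference in copy number between the knockout and control cells may account for it, but the deviation from all tested genes, 0.21, fell between the bounds set beforehand. Copy number therefore cannot be told apart from other chromosome-wide causes with RNA alone, and whether the shift follows from the loss of profilin 1 or from the history of the cells was not tested.

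Of 338 long noncoding RNAs tested, 130 were called higher and 21 lower, a larger share of increases among calls than in protein-coding genes. With median-of-ratios scaling 77.3% of the called ones were still higher (109 against 32, and 2589 against 2657 in protein-coding genes), which argues against scaling as the whole cause. With Rn45s in the model the median log2 fold change of the 130 that rose went from 0.37 to 0.27, between the bounds set for that test, so library composition that follows ribosomal RNA cannot be told apart from the knockout: the Rn45s share differs between the groups. In the same model the log2 fold change of Malat1 went from 1.47 to 0.91 and that of Neat1 from 1.39 to 1.04. Within the groups these RNAs, chosen for having risen, differed by 0.18 in control library 4 and by -0.12 in knockout library 1 from the rest of the group, and protein-coding genes by 0.08 and -0.04, so part of this is not particular to them. A response to the knockout stays open.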

How the results depend on the processing

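The log2(CPM + 0.5) scale, the fit without chromosome 2 and the fit without both control library 4 and knockout library 1 were chosen after seeing the data. Pfn1 kept its direction and call in all alternatives, at -1.57 to -1.66, and -1.57 to -1.64 on leaving out 1 library. Leaving out 1 library gave 4335 to 5485 called genes, 2888 to 3941 higher and 1447 to 1657 lower, 83 to 104 with a 2-fold change, and 7 to 10 lists past camera; without both libraries that stand apart there were 5987 called genes, 4415 higher and 1572 lower, and 9 lists. Lower genes numbered 2723 with median-of-ratios scaling. The 2-fold count was 247 with a pseudocount of 0.1, 20 with a pseudocount of 5, 53 at a mean of at least 5 RPKM and 193 on the log2(CPM + 0.5) scale, as the pseudocount and filter by construction weigh on low genes. Of the lists, 0 passed with an estimated correlation, 22 with fry for 1 direction and 33 with fry for either direction; fry does not compare a list with other genes. Glycolysis was directionally up with fry (adjusted p = 0.0328) and down, uncalled, with camera, which compares the list with other genes. The list's median was 0.02, above 0 but below the median of 0.06 of all tested genes, and its mean was 0.06. These values do not settle why the signs differ. Among 3090 values of named genes under alternatives, 0 reversed and 49 lost their call. Same-numbered libraries deviated with correlations of 0.18, 0.02, -0.19 and -0.08, so the numbers do not pair them; with the replicate block 5205 genes were called, 3477 higher and 1728 lower, 91 of them changed 2-fold, and 9 lists. DESeq2, the fits with edgeR and limma-voom were not run, since the table holds no counts; library size alone is the deposited scaling. Genes near 1 RPKM are limited by depth.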

Other observations

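Apart from the count without control library 4 and knockout library 1, the lists and tests given here had been fixed beforehand. Replication-dependent histone genes had 19 of 47 members higher and 4 lower, and 19 and 5 adjusted over the list alone, or 8 and 7 with median-of-ratios scaling, without passing camera (adjusted p = 0.663). Hist1h1d rose 1.23-fold, Hist1h2bh rose 1.22-fold and Hist1h3i fell to 80.5% of control. Mitochondrial dynamics and mitophagy genes had 11 of 26 higher and 3 lower, in both counts, or 7 and 4 with median-of-ratios scaling (adjusted p = 0.663), with Optn on chromosome 2 up 1.51-fold, the kinase gene Pink1 up 1.35-fold and Bnip3 down to 77.8%. Of 19 hypoxia response genes 3 rose and 6 fell, in both counts, or 2 and 9 with median-of-ratios scaling and 5 and 5 without control library 4 and knockout library 1 (adjusted p = 0.19), Egln3 rising 1.68-fold and Adm falling to 57.9% of control, a call lost without knockout library 2 (adjusted p = 0.0597) or 4 (0.0557).

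YAP and TEAD targets went both ways, with 11 of 23 members tested. Of these 4 were higher and 4 lower (camera adjusted p = 0.436), and 4 and 5 adjusted over the list alone. With median-of-ratios scaling 3 were higher and 5 lower. The receptor kinase gene Axl fell from 2.28 ± 0.239 to 0.475 ± 0.0104 RPKM, while F3, which encodes tissue factor, rose from 6.96 ± 1.16 to 12.8 ± 0.599 RPKM.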
